A study of Mus musculus with 33 samples.

How the data were processed

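The samples were 33 libraries of polyadenylated RNA from mouse ovary in 9 groups and 3 experiments, grouped by the genotype and stage given in the labels. Per the labels' protocols, total RNA was purified on columns and treated with DNase, the libraries of the first 2 experiments were sequenced at a university core, and those of the stage experiment were made with a KAPA kit after poly(A) selection and sequenced as paired-end reads on a NovaSeq instrument. Library kit, read length and strand setting of the first 2 experiments are not given in the sources used here. The authors deposited estimated counts per gene (expected counts, which need not be whole) in 1 table of 54347 gene identifiers and 33 libraries; 10.5% to 20.1% of the values in a library were not whole numbers. Per the submitters' processing notes the tools were Salmon and DESeq2 and the genome build was GRCm38; their versions and settings, and the annotation, are not given in the sources used here. Because counts are estimates for whole genes, reads shared by near-identical copies or pseudogenes are divided by the quantifier, and values of such genes are called uncertain. The same holds for overlapping genes.

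Counts were rounded to whole numbers. Identifiers were matched to GENCODE M21 on GRCm38 for symbols and coordinates: 53307 matched with their version and 54094 without it, and 253 had no symbol, holding 0.0055% of the counts. Total counts per library ran from 10.1 M to 23.7 M, and a count of 0 is taken to allow up to 3 counts in that library. No pair of libraries of one group agreed within sampling noise (chi-square per degree of freedom 5.6 to 73.6), so each was counted as 1 sample. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

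Each experiment was fitted apart with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group, glmQLFit with robust estimation, glmQLFTest for each of 10 contrasts, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. All groups of an experiment share the estimate of spread. CPM means and SDs for a comparison use TMM-scaled library sizes. The values per library and group used for Fshb counts and for single libraries use total counts, except where TMM scaling is stated. The difference between experiments 1 and 2 was tested in a fit over both, as rescue minus Fshb(-/-) against WT minus Fshb(-/-). Fold changes from different experiments were compared across genes by Pearson and Spearman correlation, and overlaps of calls with the number n1 × n2 / N that independent lists would share. Where a group held 1 to 3 counts of a gene in sum, the ratio of counts per total is given with a 95% exact counting interval; where it held 0, a lower bound against the floor of 3 counts per library.

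Named genes follow 1 rule. They are Fshb and the panel Fshr, Lhcgr, Cyp19a1, Star, Cyp11a1, Cyp17a1, Inha, Inhba, Amh, Pgr and Gdf9. To these are added the 8 genes up and 8 down with the largest absolute log2 fold change among those past the threshold with a mean of at least 5 CPM over both groups, no overlap between groups and no name of a predicted model or pseudogene (4 and 4 for comparisons other than Fshb(-/-) against WT, the rescue against Fshb(-/-) and those between stages). Last, up to 4 tested members with the smallest p from each fixed list may be named. Genes of the difference between experiments were chosen after their values were seen.

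The 31 lists cover ovarian cell types (granulosa and FSH response, luteal, theca and interstitial, oocyte, ovarian surface epithelium), processes (steroidogenesis, LH surge and ovulation, cell cycle, cholesterol synthesis, matrix remodelling, fibrillar collagen, hormone receptors, TGF-beta family, WNT pathway, oxidant defence, glycolysis, circadian clock, immediate early, heat shock, interferon response), other cells that a sample could hold (macrophage, neutrophil, lymphocyte, endothelium, smooth muscle, oviduct epithelium, adipocyte, skeletal muscle, erythrocyte), and RNA quality or library type (mitochondrial genome, histones). Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated; no list call in any contrast held with an estimated correlation. Lists share some genes. The oviduct index is the mean log2(CPM + 1) of the oviduct list; it and the contrast without DE replicate 3 and E replicate 3 were added after seeing the data.

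Alternatives were DESeq2 1.42.0 (genes without an adjusted p not called), limma voom with sample quality weights, median-of-ratios factors, no filter, a mean CPM of at least 1, only the groups compared, the replicate number as a block, and each replicate left out in turn. Other splits of the libraries into groups of the same sizes were refitted, with 100 drawn where more exist. The procedure was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. For Fshb(-/-) against WT over 16954 genes it recovered 55% and 84% with 10 false calls; for the rescue over 16605 genes 75% and 91% with 13; and for PE against DE over 16703 genes 60% and 80% with 8. Simulated genes varied independently, with 1 mean per gene over all groups apart from the changes, which were set in genes of at least 1 CPM. Structure shared across genes, such as that of the oviduct index, was absent, so the shares recovered may be too high for the stages. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.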

Results

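Mouse ovaries were profiled by sequencing of polyadenylated RNA in 33 libraries from 3 experiments. The question was which ovarian transcripts depend on follicle-stimulating hormone (FSH) and which follow the stage of the estrous cycle. FSH is a pituitary hormone that acts on the granulosa cells of ovarian follicles, and Fshb encodes its hormone-specific subunit. Experiment 1 held 3 libraries each of ovaries labelled wild type (WT), Fshb(+/-) and Fshb(-/-). Experiment 2 held 4 libraries labelled Fshb(-/-) and 4 labelled Fshb(-/-) HFSHB, a label that names an FSHB transgene on the mutant background and is called the rescue here. Experiment 3 held 4 libraries of each of the stages DE, PE and E, all labelled WT, and 4 libraries whose stage label reads KO (anestrus) while their genotype label reads WT. The labels do not spell out the stage names, which in usual usage stand for diestrus, proestrus and estrus. The titles of the libraries of experiments 1 and 2 hold NS in the place where those of experiment 3 hold the stage. The titles do not explain NS, so differences in stage within and between these groups cannot be excluded. The total count per library was 13.6 M to 16.9 M in experiment 1, 19.6 M to 23.7 M in experiment 2 and 10.1 M to 15.9 M in experiment 3. The labels do not say that libraries of one group came from separate animals, so the p-values below measure the spread between these samples, which may be technical in part.

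Fshb (ENSMUSG00000027120.6, chromosome 2, 107056140 to 107059656, GRCm38), the targeted gene, had more counts in the libraries labelled Fshb(-/-) than in those labelled WT of experiment 1. In experiment 1 it had 1, 1 and 0 counts in the libraries labelled WT, 43, 60 and 106 in those labelled Fshb(+/-), and 68, 79 and 82 in those labelled Fshb(-/-). In experiment 2 it had 169, 184, 176 and 119 counts in the libraries labelled Fshb(-/-) and 221, 270, 370 and 431 in those labelled rescue. In experiment 3 it had 93, 114, 93 and 90 counts in the libraries labelled KO (anestrus), 86, 70, 198 and 60 at DE, 0, 0, 51 and 26 at PE, and 50, 170, 0 and 60 at E. A count of 0 allows up to 3 counts in that library, and this limit and the intervals below cover counting error only. Counts per gene do not show which part of the gene the reads came from, so reads from the targeted allele cannot be told from those of an intact one. Groups are therefore named by their labels throughout, and each direction below rests on the labels as given.

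**Figure D1:**
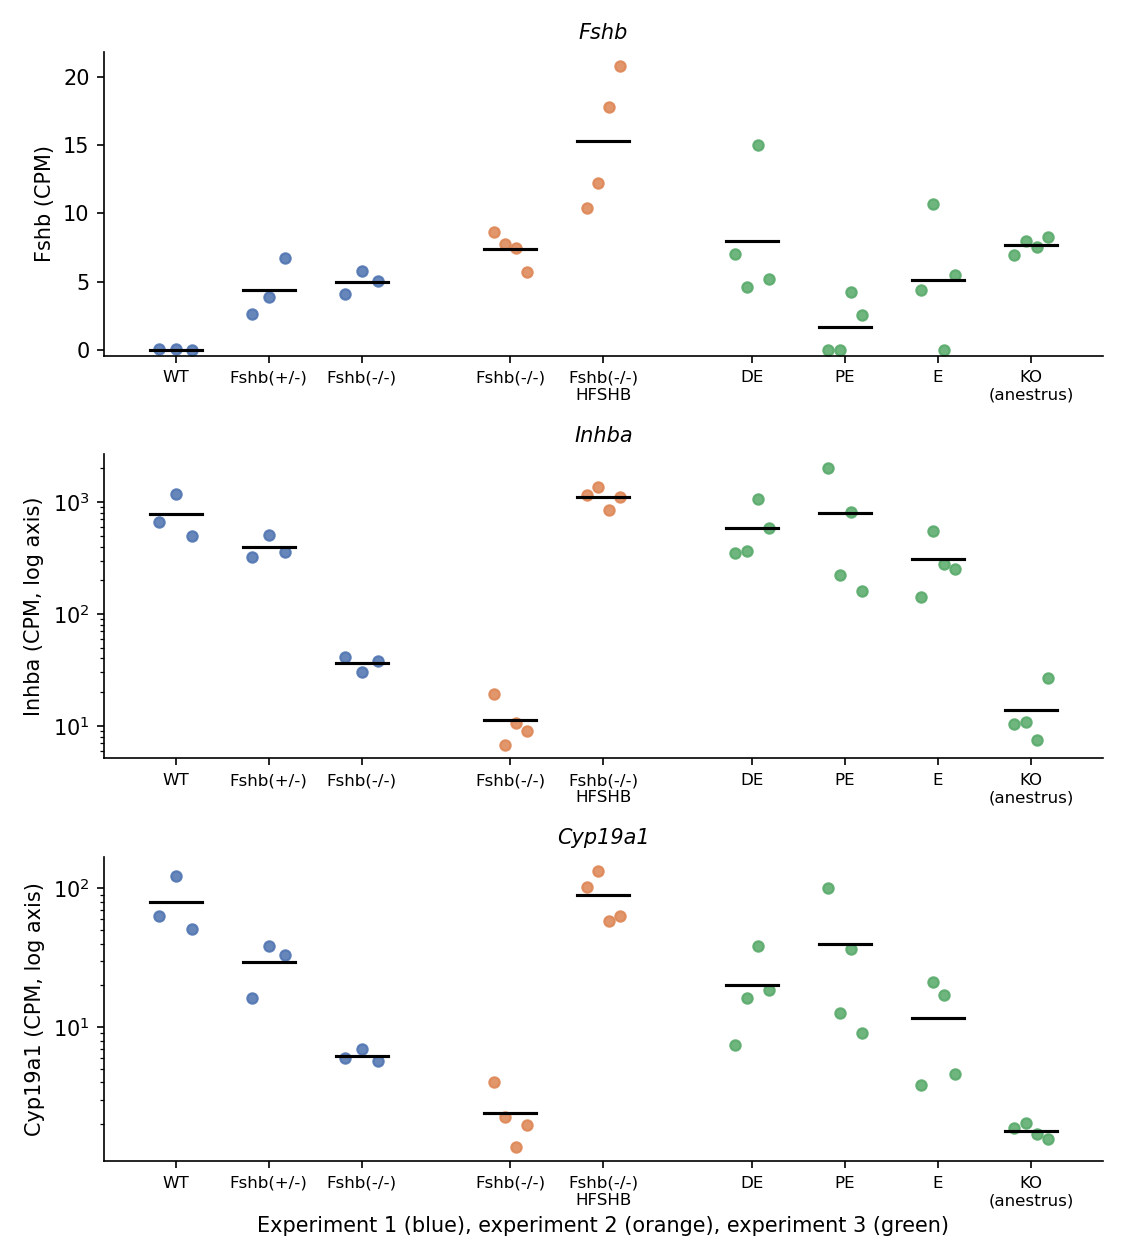
CPM (of the total count) of Fshb (linear axis), Inhba and Cyp19a1 (log axes) in each of the 33 libraries, by group, with 1 point per library and a line at the group mean. Colours mark experiments 1 (blue), 2 (orange) and 3 (green). The group means of Inhba and Cyp19a1 are lowest in the libraries labelled Fshb(-/-) or KO (anestrus) of each experiment, at 36.6, 11.4 and 13.9 CPM for Inhba.

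In the ovaries labelled Fshb(-/-) of experiment 1, transcripts of Inhba and Cyp19a1 were lower than in those labelled WT, and those of Amh were higher. Inhba, which encodes the activin A and inhibin A beta subunit (chromosome 13, 16011851 to 16031621), was at 36.4 ± 5.55 CPM against 782 ± 356 (SD, n = 3 each), a log2 fold change of -4.42 ± 0.35 (SE; edgeR quasi-likelihood test, adjusted p = 0.00075). Cyp19a1, which encodes the aromatase that makes estrogen from androgen (chromosome 9, 54165937 to 54268110), was at 6.18 ± 0.638 against 79.7 ± 38.2 CPM, a log2 fold change of -3.69 ± 0.43 (adjusted p = 0.0031). Amh, which encodes the anti-Müllerian hormone of small growing follicles, was at 971 ± 39.3 against 264 ± 66.8 CPM, a log2 fold change of 1.88 ± 0.23 (adjusted p = 0.0031). Fshb rose 124-fold by its summed counts (229 against 2; 95% counting interval 33.8 to 1030; adjusted p = 0.001).

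Other genes of hormone production split between both directions. Inhbb, which encodes the other beta subunit of inhibin and activin, fell with a log2 fold change of -3.22 ± 0.44. Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase of the ovary, fell with -1.69 ± 0.21 (adjusted p = 0.0027), while its relative Hsd3b6 rose with 3.51 ± 0.42 (adjusted p = 0.0025). Insl3, a peptide hormone of theca cells, rose from 9.44 to 167 CPM (log2 fold change 4.15 ± 0.62, adjusted p = 0.0093). Cyp11a1, which makes pregnenolone from cholesterol, fell with -1.43 ± 0.34 (adjusted p = 0.038), and Gdf9, an oocyte growth factor, rose with 0.81 ± 0.19 (adjusted p = 0.036). The Cyp11a1 call ended without any 1 of KO replicates 1, 2 and 3 or WT replicates 1 and 2 (adjusted p up to 0.14), and the Gdf9 call ended without any 1 of the 6 libraries (up to 0.12). The other panel genes did not pass: adjusted p = 0.19 for the FSH receptor gene Fshr, 0.5 for the LH receptor gene Lhcgr, 0.23 for Star, 0.57 for Cyp17a1, 0.81 for Inha and 0.16 for the progesterone receptor gene Pgr.

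Genes outside the panel are named here by size of change among those with a mean of at least 5 CPM over both groups and no overlap. Rises were in Svs5, a seminal vesicle secretory protein gene (5.53 ± 0.43, 96.7 against 2.08 CPM), Ache, which encodes acetylcholinesterase (4.93 ± 0.66), Ren1, which encodes renin (4.54 ± 0.45, 44.7 against 1.91 CPM), and Nxf3 (3.63 ± 0.27), with adjusted p = 0.00078, 0.0039, 0.0015 and 0.00048. Falls were in the glycosyltransferase gene Mgat4c (-5.21 ± 0.59, adjusted p = 0.0024) and in Grem1, a BMP antagonist (-5.20 ± 0.66, 1.83 against 68.1 CPM, adjusted p = 0.0045). Lcn2, which encodes lipocalin 2, rose with 4.18 (adjusted p = 0.024). Wnt10b (-6.97, 0.636 against 82.0 CPM, adjusted p = 0.036), the cell adhesion gene Nrcam (-6.22, 0.043), Nap1l2 (-5.00, 0.048), the transcription factor gene Runx2 (-4.52, 0.04) and the lipid droplet gene Plin4 (-4.36, 0.047) fell. These 6 calls each ended without any 1 of KO replicates 1, 2 and 3 or WT replicates 1 and 2, with an adjusted p up to 0.15. The size of some falls also hung on 1 library: without WT replicate 2 Nap1l2 was at -2.99 and Plin4 at -2.98, and without WT replicate 1 Runx2 was at -3.39. By total counts, Wnt10b ran from 1.54 to 146 CPM in the libraries labelled WT and from 0.425 to 1.06 in those labelled Fshb(-/-), so the groups nearly met. Rps3a2 and Rps3a3, near-identical copies of the ribosomal protein gene Rps3a1, rose with 9.33 and 7.25, which is uncertain because reads can be split between the copies. Their values summed with Rps3a1 were 1120 ± 164 CPM in the libraries labelled Fshb(-/-) and 825 ± 62.1 CPM in those labelled WT.

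Of the lists of genes fixed in advance, the oocyte list rose: 20 of 33 tested members passed over all genes, 31 adjusted over the list alone, all higher (camera adjusted p = 4.1e-21, and adjusted p = 0.41 with an estimated correlation). Examples are Dppa3 (1.03 ± 0.14), Bcl2l10 (0.87 ± 0.13), H1foo (0.96 ± 0.14) and Tcl1 (0.96 ± 0.15). Of 34 cell cycle genes 8 rose, 27 adjusted over the list alone (adjusted p = 5.5e-13, and adjusted p = 0.41 with an estimated correlation). An example is the spindle checkpoint kinase gene Bub1b (0.82 ± 0.14). In steroidogenesis 1 of 20 rose and 4 fell (1 and 7 adjusted over the list alone; adjusted p = 4e-05, lower, and adjusted p = 0.41 with an estimated correlation). In the endothelium list 2 of 18 rose and 8 fell (3 and 13 adjusted over the list alone; adjusted p = 8.7e-05, lower, and adjusted p = 0.41 with an estimated correlation). Examples are the endothelial adhesion genes Cdh5 (-0.70 ± 0.09) and Pecam1 (-0.89 ± 0.14). In the luteal cell list 1 of 20 rose and 3 fell (1 and 10 adjusted over the list alone; adjusted p = 0.00014, lower, and adjusted p = 0.41 with an estimated correlation). In the circadian clock list 1 of 18 rose and 5 fell (3 and 8 adjusted over the list alone; adjusted p = 0.015, lower, and adjusted p = 0.41 with an estimated correlation). An example is Nr1d1 at -0.98 ± 0.12. In the WNT pathway 0 of 24 rose and 5 fell (2 and 9 adjusted over the list alone; adjusted p = 0.027, lower, and adjusted p = 0.41 with an estimated correlation). Examples are the receptor gene Fzd4 (-1.03 ± 0.15) and Rnf43 (-1.47 ± 0.24). The circadian clock and WNT lists both had adjusted p = 0.053 without KO replicate 2.

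The remaining lists did not pass with the preset correlation. Among granulosa and FSH response genes 5 of 30 rose and 7 fell (5 and 8 adjusted over the list alone). Among TGF-beta family genes 4 of 30 rose and 6 fell (4 and 8 adjusted over the list alone), and among LH surge and ovulation genes 7 of 25 rose and 3 fell (8 and 6 adjusted over the list alone). Has2, which makes hyaluronan, rose with 3.39 ± 0.45. Theca and interstitial cell genes had 3 of 18 higher and 1 lower (4 and 1 adjusted over the list alone), with Pdgfra at 1.41 ± 0.23. Matrix remodelling genes had 3 of 23 higher and 1 lower (6 and 3 adjusted over the list alone), with the protease gene Adamts15 at 2.50 ± 0.24. Fibrillar collagen and matrix genes had 1 of 20 higher and 3 lower (the same adjusted over the list alone), with Fn1, which encodes fibronectin, at -1.12 ± 0.15 and Lum at -1.76 ± 0.23. Hormone receptors had 2 of 18 higher and 1 lower (2 and 7 adjusted over the list alone). Members higher and lower numbered 1 and 2 of 23 in glutathione and oxidant defence and 0 and 2 of 22 in glycolysis and hypoxia. They numbered 1 and 1 in ovarian surface epithelium, of 12, and in neutrophil and acute inflammation, of 9. The macrophage list had 1 of 18 higher and the adipocyte list 1 of 10 lower. No member passed among 24 cholesterol synthesis, 20 interferon response, 19 immediate early, 14 lymphocyte, 12 heat shock, 12 oviduct epithelium, 11 smooth muscle, 5 erythrocyte and 4 skeletal muscle genes, nor among 13 mitochondrial genome and 6 histone genes, which track RNA quality and library type.

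In all, 1355 of 17223 genes passed at an adjusted p under 0.05, 780 higher and 575 lower in the libraries labelled Fshb(-/-), and 656 of them differed by at least 2-fold. The groups did not overlap in 35.3% of genes, where chance gives 10%. The count was 456, 597 and 488 without KO replicates 1, 2 and 3, and 518 and 526 without WT replicates 1 and 2. WT replicate 3 stood apart from the others of its group in luteal genes, with Sfrp4 at 44.2 CPM against 2730 and 3220.

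Between ovaries labelled Fshb(+/-) and WT in experiment 1, 15 genes passed the test, Fshb among them. Fshb was 110-fold higher by its summed counts (209 against 2; 95% counting interval 30 to 913; adjusted p = 0.0058). Glo1, which encodes the methylglyoxal-detoxifying glyoxalase 1, rose with a log2 fold change of 0.85 ± 0.11 (160 against 88.5 CPM, n = 3 each), and Nt5e, which encodes the ectoenzyme CD73, with 1.13 ± 0.14 (15 against 6.84 CPM), both with adjusted p = 0.028 by edgeR. The Glo1 call ended without any 1 of the 6 libraries (adjusted p up to 0.16) and the Nt5e call without any 1 but Het replicate 2 (up to 0.14). All 15 were higher in edgeR, whereas DESeq2 called 363 genes, 179 higher and 184 lower, and limma voom 29, 23 higher and 6 lower. The other 12 of the 15 are predicted gene models or pseudogenes, whose reads may be shared with near-identical copies.

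No list had a member past the threshold over all genes. Even so, 14 lists passed camera with the preset correlation and 0 with an estimated one. The oocyte list was lower (11 of 33 lower adjusted over the list alone; adjusted p = 1.7e-13, and adjusted p = 0.38 with an estimated correlation), as were granulosa and FSH response genes (5 of 30 lower adjusted over the list alone; adjusted p = 2.4e-08, and adjusted p = 0.079 with an estimated correlation). The WNT pathway (1 of 24 higher and 1 lower adjusted over the list alone) and fibrillar collagen (1 of 20 higher) were higher, both with adjusted p = 4.3e-05, and with an estimated correlation adjusted p = 0.073 and 0.14. The oviduct epithelium list was higher (adjusted p = 0.00024, and adjusted p = 0.56 with an estimated correlation), and this was lost without Het replicate 3 (0.82), whose mean log2(CPM + 1) over the oviduct list, the oviduct index, was 5.17 against a mean of 1.33 in the libraries labelled WT. The mitochondrial genome list, which tracks RNA quality, was lower (0 members adjusted over the list alone; adjusted p = 0.0081, and adjusted p = 0.69 with an estimated correlation), which ended without Het replicate 1 (0.19). Among lists of other cells, macrophage genes were higher (0 members adjusted over the list alone; adjusted p = 0.036, and adjusted p = 0.77 with an estimated correlation), which ended without WT replicates 1 (0.2) or 2 (0.1) and turned without Het replicate 2 (0.86). Ovarian surface epithelium (0.00051) and luteal genes (0.0078) were higher, with 2 and 0 members adjusted over the list alone and adjusted p = 0.38 each with an estimated correlation. The surface epithelium call ended without Het replicate 3 (0.076), and the luteal call without Het replicate 3 (0.19) or WT replicate 3 (0.15). Interferon response (9.3e-05, higher) and TGF-beta family genes (0.011, lower), with 0 members higher and 1 higher and 4 lower adjusted over the list alone, had adjusted p = 0.38 and 0.14 with an estimated correlation. The other 3 lists were matrix remodelling, glycolysis and hypoxia, and circadian clock (adjusted p = 0.015, 0.024 and 0.025, all higher; 0, 0 and 3 members higher and 0, 0 and 1 lower adjusted over the list alone), with adjusted p = 0.38, 0.52 and 0.51 with an estimated correlation. Their calls ended without Het replicate 1 (0.05, 0.41 and 0.18) and without others: for matrix, Het replicate 2 (0.11) or WT replicate 1 (0.14), for glycolysis WT replicate 3 (0.068), and for the clock Het replicate 3 (0.1) or WT replicate 2 (0.11). At an unadjusted p under 0.05 there were 1783 genes, and the count was 9 without WT replicate 3; 15.3% of genes had groups that did not overlap, where chance gives 10%.

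Set against Fshb(+/-), the ovaries labelled Fshb(-/-) had fewer transcripts of Inhba and Cyp19a1 and more of Amh and Gdf9. Granulosa and FSH response genes moved both ways, 9 of 30 higher and 6 lower, and did not pass as a list (adjusted p = 0.5). Inhba was at 36.4 against 396 CPM (log2 fold change -3.44 ± 0.33, n = 3 each, adjusted p = 0.00061), Cyp19a1 at 6.18 against 29.4 CPM (-2.25 ± 0.41, adjusted p = 0.0094), Amh at 971 against 200 CPM (2.28 ± 0.24, adjusted p = 0.00071) and Gdf9 at 147 against 60.7 CPM (1.27, adjusted p = 0.0033). Fshb did not pass (0.16). Svs5 (6.08 ± 0.45), Insl3 (4.51), Ache (4.66) and Hsd3b1 (-1.97) passed as well, and Rps3a2 (8.14) is uncertain as above. Cyp11a1 (-1.73, adjusted p = 0.011) and Wnt10b (-7.96, adjusted p = 0.013) fell, and both calls ended without KO replicate 1 (0.053 and 0.06). Fshr rose (1.08, adjusted p = 0.021) until any 1 of Het replicates 1 and 2 or KO replicates 1 and 2 was left out (up to 0.078), and Inha (0.70, adjusted p = 0.033) until any 1 but Het replicate 1 was (up to 0.097). The prostaglandin F receptor gene Ptgfr fell (-6.82, adjusted p = 0.028), which ended without any 1 but Het replicate 1 (up to 0.097). Pik3c2g (-7.25, 0.048) fell, which ended without any 1 of the 6 libraries (up to 0.14), and Gpr141 (-6.58, 0.017) fell, which ended without KO replicates 1, 2 or 3 (up to 0.075).

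Oocyte genes were higher, 30 of 33 over all genes and 31 adjusted over the list alone (camera adjusted p = 9.7e-33, and adjusted p = 0.17 with an estimated correlation). Examples are Dppa3 (1.61), Bcl2l10 (1.42) and Oosp1 (1.63). Cell cycle genes were higher in 20 of 34 (28 adjusted over the list alone; adjusted p = 1.6e-12, and adjusted p = 0.48 with an estimated correlation). Examples are Bub1b (1.15) and Nusap1 (1.20). Lists lower with the preset correlation were luteal cells (1 higher and 8 lower of 20, 1 and 15 adjusted over the list alone; adjusted p = 1.8e-06), WNT pathway (2 and 11 of 24, 3 and 13; 2.3e-05) and fibrillar collagen (0 and 6 of 20, 0 and 7; 0.00019). They had adjusted p = 0.17, 0.063 and 0.17 with an estimated correlation. So were endothelium (1 and 11 of 18, 2 and 11 adjusted over the list alone; 0.00056), circadian clock (3 and 8 of 18, 3 and 10; 0.00069) and steroidogenesis (1 and 7 of 20, 3 and 12; 0.0015). These had adjusted p = 0.48, 0.38 and 0.45 with an estimated correlation. Examples are the matrix gene Fn1 at -2.00 and the clock genes Nr1d1 at -1.56 and Dbp at -2.40. Theca cells were higher (4 and 1 of 18, 7 and 2 adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.17 with an estimated correlation). The interferon response was lower (0 and 3 of 20, 0 and 4 adjusted over the list alone; adjusted p = 0.03, and adjusted p = 0.81 with an estimated correlation), and this was lost without Het replicate 2 (0.072), Het replicate 3 (0.057) or KO replicate 3 (0.15). In all 2928 genes passed, 1568 higher and 1360 lower, and 1362, 1888 and 1563 without KO replicates 1, 2 and 3. The groups did not overlap in 37.7% of genes, where chance gives 10%. Het replicate 3, with the high oviduct index, lies in this comparison as well. Of the 2928 genes passed, 26 also follow the index, a smaller share than among all genes tested (360 of 17223).

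**Figure D2:**
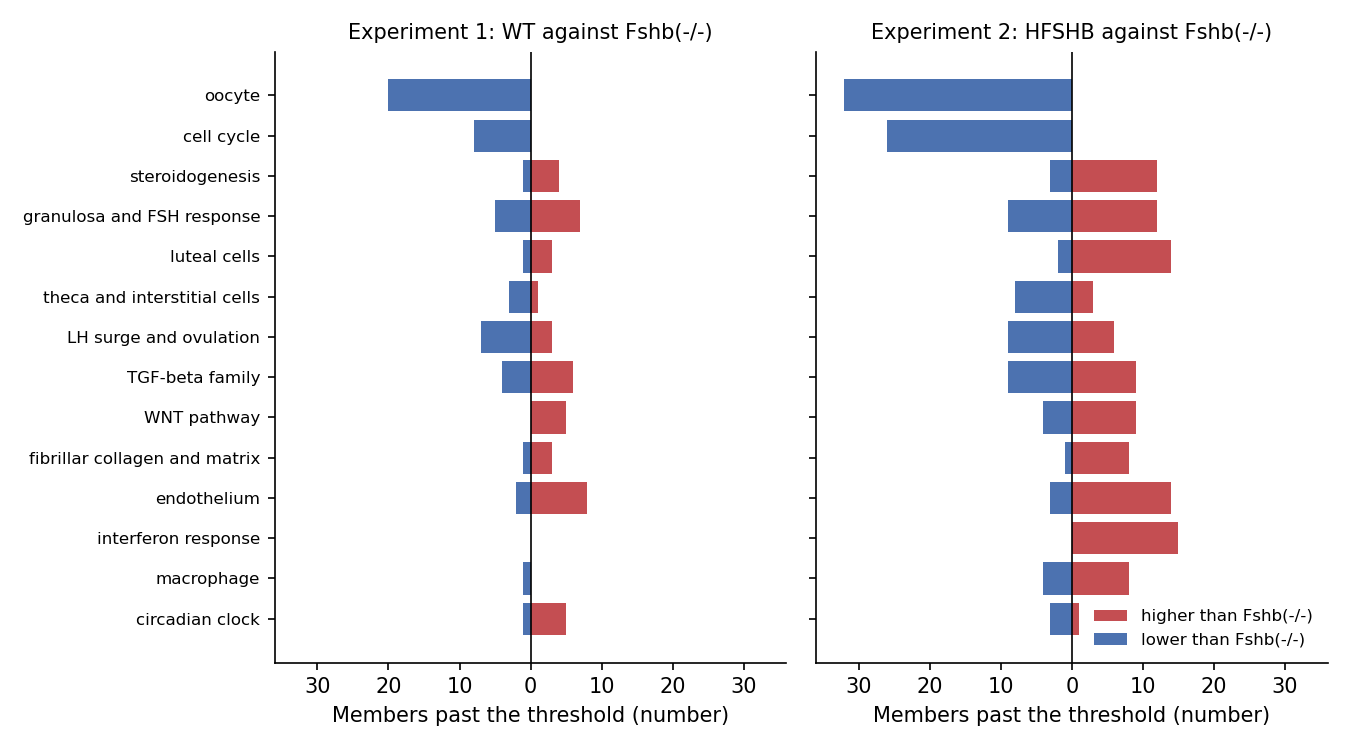
Number of tested members of 14 fixed gene lists that were higher (red, to the right) or lower (blue, to the left) than in the libraries labelled Fshb(-/-) at an adjusted p under 0.05, for WT in experiment 1 (left) and the rescue, labelled HFSHB, in experiment 2 (right). Oocyte genes were lower in 20 of 33 for WT and in 32 of 33 for the rescue.

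In experiment 2, the ovaries labelled rescue had more transcripts of Inhba and Cyp19a1 than those labelled Fshb(-/-), and fewer of Amh and Gdf9. Inhba was at 1130 ± 196 against 11.3 ± 5.42 CPM (SD, n = 4 each), a log2 fold change of 6.65 ± 0.38 (edgeR adjusted p = 3.5e-05). Cyp19a1 was at 90.3 ± 33.9 against 2.38 ± 1.15 CPM (5.26 ± 0.41, adjusted p = 0.00013) and Inhbb rose with 2.89 ± 0.22. Cyp11a1 was at 5630 against 1480 CPM (1.93 ± 0.25, adjusted p = 0.0011), while Amh fell (-1.56 ± 0.23, adjusted p = 0.002), as did Gdf9 (-0.86 ± 0.16, 0.0052) and Cyp17a1, which makes androgen precursors in theca cells (-2.16 ± 0.44, 0.01). Fshb was higher in the rescue, at 15.6 ± 5.36 against 7.33 ± 1.2 CPM (1.09 ± 0.24, adjusted p = 0.01).

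Lhcgr rose (1.35 ± 0.40, adjusted p = 0.038), a call that ended without any 1 of the 4 KO replicates or of Rescue replicates 3 and 4 (up to 0.096). Star (adjusted p = 0.052), Inha (0.096), Pgr (0.25) and Fshr (0.76) did not pass. Wnt10b was at 93.2 against 0.0695 CPM (log2 fold change 10.31 ± 0.41, adjusted p = 6.2e-06). Akr1c18, which inactivates progesterone (9.35 ± 1.13, 115 against 0.172 CPM), Ptgfr (8.48 ± 0.92, 785 against 2.22 CPM) and the WNT antagonist gene Sfrp4 (7.54 ± 0.69, 1730 against 9.32 CPM), all known from luteal cells, rose as well. The rescue libraries split in these genes, given here in CPM with TMM-scaled library sizes for Rescue replicates 1 and 2 against 3 and 4. Ptgfr was at 232 and 360 against 1120 and 1420, Sfrp4 at 766 and 1180 against 2170 and 2810, and Lhcgr at 623 and 686 against 1560 and 1710. Akr1c18 went the other way, at 150 and 211 against 21.4 and 76.4. Where the libraries labelled Fshb(-/-) held 1 to 3 counts in sum, the ratio of counts was 6690 for the tight junction gene Cldn18 (95% counting interval 1200 to 264000), 1810 for Bpifb6 (501 to 15000), 1040 for Onecut2 (288 to 8600) and 564 for Ces2a (193 to 2740). The Cldn18 call ended without KO replicate 2 (0.074) and the Bpifb6 call without any 1 KO replicate (up to 0.072). Svs5 (-5.71 ± 0.28), Svs6 (-6.16 ± 0.62), Insl3 (-6.03 ± 0.48, 3.09 against 204 CPM), Hsd17b3, which makes testosterone (-6.86 ± 0.72), L3mbtl4 (-5.35 ± 0.20) and Lcn2 (-4.89 ± 1.02) fell. The adrenal-type hydroxylase gene Cyp21a1 was 919-fold lower (164 to 36300) and the kallikrein gene Klk1b24 307-fold lower (105 to 1490) by counts.

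Of 33 oocyte genes 32 were lower in the rescue and 0 higher, the same adjusted over the list alone (camera adjusted p = 1.4e-15, and adjusted p = 0.49 with an estimated correlation). Examples are Kit (-1.29 ± 0.13), Ooep (-1.06 ± 0.12) and Padi6 (-1.28 ± 0.15). Of 34 cell cycle genes 26 were lower (29 adjusted over the list alone; adjusted p = 9.3e-08, and adjusted p = 0.5 with an estimated correlation), by small amounts such as -0.43 ± 0.06 for the replication helicase gene Mcm2. In steroidogenesis 12 of 20 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 2.8e-07, and adjusted p = 0.26 with an estimated correlation). Examples are the electron carrier genes Fdxr at 1.20 ± 0.07 and Fdx1 at 1.28 ± 0.15. In luteal cells 14 of 20 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 1.7e-05, and adjusted p = 0.49 with an estimated correlation), with a mean log2(CPM + 1) of 7.29 and 7.57 in Rescue replicates 1 and 2 and 8.36 and 8.57 in 3 and 4, against 5.92 to 6.12 in KO. Theca and interstitial genes fell in 8 of 18 and rose in 3 (10 and 4 adjusted over the list alone; adjusted p = 0.00046, and adjusted p = 0.32 with an estimated correlation). Examples are Pdgfra at -1.86 ± 0.10 and the hedgehog receptor gene Ptch1 at -0.82 ± 0.09. In granulosa and FSH response 12 of 28 rose and 9 fell (13 and 9 adjusted over the list alone; adjusted p = 0.0083, higher, and adjusted p = 0.49 with an estimated correlation), and the list call ended without KO replicate 3 (0.065) or Rescue replicate 1 (0.053).

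Interferon response genes rose in 15 of 20 (16 adjusted over the list alone; adjusted p = 4.1e-07, and adjusted p = 0.49 with an estimated correlation). Examples are Irf7 (0.99 ± 0.14), Ifi44 (2.05 ± 0.33) and Oas2 (1.67 ± 0.27). The 5 erythrocyte genes tested all rose, also adjusted over the list alone (adjusted p = 0.00054, and adjusted p = 0.49 with an estimated correlation). An example is Alas2 at 1.70. Endothelium genes rose in 14 of 18 and fell in 3, the same adjusted over the list alone (adjusted p = 0.0025, and adjusted p = 0.55 with an estimated correlation). An example is Pecam1 at 0.96 ± 0.09. Collagen and matrix genes rose in 8 of 20 and fell in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.5 with an estimated correlation). Examples are Lum at 1.71 ± 0.08 and Tnc, which encodes tenascin C, at 2.91 ± 0.39. Ovarian surface epithelium genes fell in 10 of 12 and rose in 1, the same adjusted over the list alone (adjusted p = 0.00017, and adjusted p = 0.49 with an estimated correlation). Examples are Upk3b at -0.92 ± 0.12 and Wt1 at -0.95 ± 0.12. Cholesterol synthesis genes rose in 2 of 24 (0 adjusted over the list alone; adjusted p = 0.0049, and adjusted p = 0.67 with an estimated correlation). An example is the sterol isomerase gene Ebp (adjusted p = 0.047), whose call ended without any 1 KO replicate or Rescue replicates 3 or 4 (up to 0.12). The rescue libraries split here: the list's mean log2(CPM + 1) was 7.45 and 7.60 in Rescue replicates 3 and 4 but 5.55 and 5.79 in replicates 1 and 2, against 5.67 to 5.91 in KO. Star split the same way, at 3390 and 4040 against 276 and 447 CPM. Heat shock genes rose in 6 of 12 and fell in 1, the same adjusted over the list alone (adjusted p = 0.029, and adjusted p = 0.5 with an estimated correlation).

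The WNT pathway rose in 9 of 24 and fell in 4 (9 and 5 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.49 with an estimated correlation). An example is the stem cell receptor gene Lgr5 at 1.68 ± 0.18. This call ended without KO replicate 3 (0.065) or KO replicate 4 (0.054), the libraries of their group with the highest oviduct index (4.03 and 2.35). Histone genes rose in 4 of 5 (5 adjusted over the list alone; adjusted p = 0.035, and adjusted p = 0.51 with an estimated correlation), which ended without Rescue replicate 4 (0.066). The adipocyte list passed as higher (3 of 11 over all genes, 2 adjusted over the list alone; adjusted p = 0.044, and adjusted p = 0.59 with an estimated correlation) although its median and mean log2 fold change were -0.77 and -0.14. It ended without KO replicate 3 (0.42), KO replicate 4 (0.29), Rescue replicate 2 (0.067) or Rescue replicate 3 (0.059). Macrophage genes (8 higher and 4 lower of 18; 9 and 4 adjusted over the list alone; adjusted p = 0.054) did not pass as a list. In all, 5390 of 16871 genes passed, 2659 higher and 2731 lower in the rescue, of which 1403 differed by at least 2-fold. The groups did not overlap in 34.3% of genes, where chance gives 2.86%.

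The changes in experiments 1 and 2 ran in the same direction for most genes. Across 16316 genes tested in both, the log2 fold change of WT over Fshb(-/-) in experiment 1 and of the rescue over Fshb(-/-) in experiment 2 had a Pearson r of 0.74 and a Spearman rho of 0.70, where genes are not independent replicates. Of the 1326 genes called in experiment 1 and tested in experiment 2, 97.4% had the same sign. Of these, 464 were called higher in both, where independent lists would share 90.9, and 646 lower in both, where they would share 125.8; 10 were called in opposite directions. A test of the difference between the 2 distances from Fshb(-/-) called 28 of 18255 genes. With signs kept, the rescue effect was above the WT effect in 9 of them and below it in 19. The count was 18 without Exp2 KO replicate 4 or without Rescue replicate 4. Among the panel only Fshb passed, with a difference of 7.81 ± 0.68 (adjusted p = 2.8e-05), which in the fit sets 1.09 in experiment 2 against -6.69 in experiment 1. Inhba had a difference of 2.22 (adjusted p = 0.11). Amd2 had a difference of 7.82 (-3.69 for WT and 4.13 for the rescue), which is uncertain because reads can be shared with the similar gene Amd1. Other genes that differed are Jmjd7 (2.49 for WT and -2.66 for the rescue), which lies on chromosome 2 as Fshb does, Pla2g4b (difference -4.23), and Eif3j1 (0.94 and -1.32); Eif3j1 has a near-identical copy, Eif3j2, so its value is uncertain.

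In experiment 3, all 3 stages had more transcripts of Inhba and Cyp19a1 than the libraries labelled KO (anestrus). Granulosa and FSH response genes moved both ways, with 6, 5 and 7 of 29 higher and 7, 8 and 6 lower at DE, PE and E, and did not pass as a list (adjusted p = 0.66, 0.3 and 0.71). Inhba was at 592 ± 330 CPM at DE, 799 ± 862 at PE and 307 ± 177 at E against 14.1 ± 8.8 in KO (SD, n = 4 each), log2 fold changes of 5.40 ± 0.85, 5.83 ± 0.87 and 4.45 ± 0.82 (edgeR adjusted p = 0.00096, 0.00054 and 0.0024). Cyp19a1 rose with 3.46 ± 0.83 at DE, 4.43 ± 0.86 at PE and 2.67 ± 0.82 at E (adjusted p = 0.01, 0.0025 and 0.036), where the call at E ended without any 1 of E replicates 2 and 3 or the 4 KO replicates (up to 0.096) and without the 2 libraries apart in oviduct transcripts (0.067). Amh fell with -2.04, -2.62 and -1.73 (adjusted p = 0.00089, 0.00015 and 0.0023), from 396 ± 65 CPM in KO. Pgr, a gene that the LH surge is known to induce in granulosa cells, rose with 6.01 ± 1.26 at DE and 6.09 ± 1.26 at PE (adjusted p = 0.0051 and 0.0036), at 73.7 and 77.4 against 1.14 CPM, and did not pass at E (0.062). With the oviduct index as a covariate, the Pgr values at DE and PE were 3.27 (adjusted p = 0.068) and 2.90 (0.18), so that neither passed. The index does not overlap between PE (4.94 to 5.58) and KO (1.29 to 1.96), which widens the error of that fit, so a call lost at PE does not by itself show that a gene followed the index. Within groups the index varied mainly through DE replicate 3 and E replicate 3 (SD 1.95 at DE and 1.94 at E, against 0.3 at PE and 0.35 in KO). If the labels of these libraries were exchanged, which is left open below, the covariate would also take up the stage.

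Cyp11a1 rose at E to 4580 ± 1720 from 1180 ± 166 CPM (1.96 ± 0.34, adjusted p = 0.0017). At DE (1.13, 0.027) its call ended without DE replicate 1 or KO replicates 1, 3 or 4 (up to 0.065), and at PE (0.91, 0.049) without any 1 of 7 libraries, all but PE replicate 4 (up to 0.19). Gdf9 fell at DE and PE (-1.52 and -1.68, adjusted p = 0.0046 and 0.002) and missed the threshold at E (-0.92, 0.052). With the oviduct index as a covariate Gdf9 (-1.13, adjusted p = 0.12), Hsd17b3 (-4.79, 0.062) and Insl3 (-3.99, 0.12) kept their direction and did not pass at PE. Star passed at E alone among the 3 comparisons (2.67, 0.044), a call that ended without any 1 of 7 libraries, all but E replicate 3 (up to 0.13). Cyp17a1 fell at E to 9.73 from 885 ± 182 CPM (-6.48 ± 1.69, 0.017), which ended without E replicate 4 (0.052). Wnt10b (9.79, 8.72 and 9.81 at DE, PE and E), Akr1c18 (9.64, 9.16 and 10.19), Ptgfr (8.11 and 7.41 at DE and PE), Sfrp4 (7.02 and 6.18 at DE and PE) and Stc1, which encodes stanniocalcin 1 (3.42 and 3.38 at DE and PE), rose. Svs5 (-6.39, -6.57 and -7.20), Svs6 (-6.90 and -7.30 at DE and PE), Hsd17b3 (-6.08 and -6.42 at DE and PE), L3mbtl4 (-5.38 at DE), Insl3 (-5.17 and -5.27 at DE and PE) and Eppin, a protease inhibitor gene (-6.54 ± 0.54 at E), fell. At E, Svs6 was 365-fold lower by counts (101 to 3020), and Cldn18, at 11.3 CPM with 0 counts in every KO library, was at least 47.3-fold higher against a floor of 3 counts per library. Onecut2 rose at DE (8.81) and E (9.32).

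At PE, Dcpp3 was 829-fold higher by counts (283 to 4020) and A2ml1 rose with 8.78 ± 2.70 (adjusted p = 0.023), which ended without any 1 KO replicate (up to 0.065). Neither passed with the oviduct index as a covariate, where Dcpp3 had 3.97 (adjusted p = 0.57) and A2ml1 -0.98 (0.81). As above, a call lost at PE does not by itself show that a gene followed the index. The index was 4.17 at DE, 5.24 at PE and 2.06 at E on average, against 1.63 in KO. Of the genes that passed, 1063 of 4249 at DE, 1476 of 5724 at PE and 311 of 3042 at E also followed the index within groups. Of all genes tested, 2467 of 16944 did, a smaller share than at DE and PE and a larger one than at E. Of the 16 oviduct epithelium genes tested, 15 rose at DE and 14 at PE (15 each adjusted over the list alone; camera adjusted p = 0.0001 and 4.4e-06, and adjusted p = 0.52 and 0.53 with an estimated correlation). An example is the cilium gene Rsph1 (2.92 and 3.52). At E 0 of the 16 passed, also 0 adjusted over the list alone (adjusted p = 0.41). Smooth muscle genes rose in 8 of 12 at DE and 7 at PE and fell in 1 each (10 and 8 higher and 1 lower each adjusted over the list alone). The smooth muscle list had adjusted p = 0.0024 and 0.006, and adjusted p = 0.52 and 0.55 with an estimated correlation. Ovarian surface epithelium genes rose in 6 of 12 at DE and 7 at PE and fell in 1 each (7 higher and 1 lower each adjusted over the list alone). The surface epithelium list had adjusted p = 0.033 and 0.0058, and adjusted p = 0.61 and 0.54 with an estimated correlation. At DE its call ended without DE replicates 1 (0.18) or 2 (0.055) or KO replicates 1 (0.057) or 4 (0.092). With the index as a covariate, smooth muscle (0.25 and 0.93) and surface epithelium (0.62 and 0.42, turned to lower) did not pass at DE and PE; the oviduct list, whose mean is the index, cannot be tested this way.

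Oocyte genes were lower than in KO in 31 of 33 at DE, 33 at PE and 11 at E (33, 33 and 30 adjusted over the list alone). The oocyte list had adjusted p = 5.5e-24, 1.5e-19 and 1.9e-09, and adjusted p = 0.36, 0.53 and 0.65 with an estimated correlation. Examples are Padi6 (-1.86 at DE and -1.91 at PE), Ooep (-1.73 and -1.87) and, at E, Kit (-1.50). Cell cycle genes were lower in 7 of 34 at DE, 29 at PE and 0 at E (0, 30 and 0 adjusted over the list alone). As a list, cell cycle had adjusted p = 1.6e-05, 6.8e-11 and 0.0023, and adjusted p = 0.52, 0.53 and 0.89 with an estimated correlation. Examples at PE are Nusap1 and Ccnb1, which encodes cyclin B1, both at -1.28. With the oviduct index as a covariate, Padi6 (-1.45, adjusted p = 0.06), Ooep (-1.28, 0.052), Nusap1 (-0.88, 0.14) and Ccnb1 (-0.88, 0.19) kept their direction and did not pass at PE. Luteal genes rose in 10 of 20 at DE, 8 at PE and 13 at E and fell in 1, 1 and 0 (10, 9 and 14 higher and 1 lower each adjusted over the list alone). The luteal list had adjusted p = 1.6e-05, 0.0029 and 5.3e-10, and adjusted p = 0.36, 0.53 and 0.16 with an estimated correlation. Steroidogenesis rose in 9 of 20 at E and fell in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.00035, and adjusted p = 0.45 with an estimated correlation). An example is Hsd3b1 at 1.56 ± 0.23. At DE it rose in 6 and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.039, and adjusted p = 0.52 with an estimated correlation), which ended without DE replicate 3 (0.41) or KO replicates 1 (0.07) or 4 (0.12), and at PE it did not pass (0.1).

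Theca and interstitial genes fell in 4, 6 and 7 of 18 and rose in 1, 1 and 2 (4, 7 and 7 lower and 1, 1 and 2 higher adjusted over the list alone). As a list, theca genes had adjusted p = 0.0034, 0.0028 and 0.0065, and adjusted p = 0.22, 0.17 and 0.16 with an estimated correlation. An example is Pdgfra at -2.03, -2.03 and -1.59. Interferon response genes rose in 4, 11 and 5 of 20 (4, 13 and 12 adjusted over the list alone). The interferon list had adjusted p = 0.0017, 0.00012 and 3.9e-05, and adjusted p = 0.52, 0.53 and 0.65 with an estimated correlation. An example is Ifi44 at 1.60 at PE, which had 0.85 with the oviduct index as a covariate and did not pass (0.29). Endothelium rose in 10, 6 and 8 of 18 and fell in 1, 2 and 2 (14, 7 and 10 higher and 2, 3 and 2 lower adjusted over the list alone). As a list, endothelium had adjusted p = 0.00074, 0.044 and 0.0033, and adjusted p = 0.52, 0.59 and 0.66 with an estimated correlation, and its call at PE ended without KO replicate 1 (0.08) or PE replicate 2 (0.066). The WNT pathway rose in 10, 12 and 10 of 24 and fell in 2, 3 and 2 (13, 13 and 10 higher and 3 lower each adjusted over the list alone). The WNT list had adjusted p = 0.015, 0.0096 and 0.0022, and adjusted p = 0.52, 0.53 and 0.51 with an estimated correlation, and its call at DE ended without DE replicate 1 (0.085). At PE 8 of 18 macrophage genes rose, the same adjusted over the list alone (adjusted p = 0.0029, and adjusted p = 0.53 with an estimated correlation). An example is Lyz2, which encodes lysozyme, at 1.82. In all, 4249, 5724 and 3042 of 16944 genes passed at DE, PE and E, 2288, 2969 and 1521 of them higher. With the oviduct index as a covariate, 1618 passed at DE, 682 higher and 936 lower, and 934 at PE, 396 higher and 538 lower. The groups did not overlap in 25.4%, 41.5% and 29.8% of genes, where chance gives 2.86%. The DE count was 2618 and 2808 without DE replicates 1 and 4 and 2480, 2805, 2422 and 2555 without KO replicates 1 to 4, and the E count was 2024, 2020 and 1920 without KO replicates 1, 3 and 4. The genotype conflict in the labels of the KO (anestrus) libraries remains in each of these comparisons, which share those 4 libraries.

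Between the cycling stages, no single gene passed in edgeR with all libraries and no covariate, and the counts moved with the tool and with single libraries. Inhba had a log2 fold change of 0.43 from DE to PE and -1.38 from PE to E, Pgr of -2.60 ± 1 from PE to E, and the theca gene Cyp17a1 of -4.85 ± 1.57 from PE to E, and none passed (edgeR adjusted p = 1, 0.3, 0.22 and 0.2, n = 4 each). Between PE and DE, E and PE, and DE and E, 0 of 16944 genes passed, with 407, 3170 and 1797 at an unadjusted p under 0.05. DESeq2 called 0, 363 and 10 genes and limma voom with quality weights 0, 2251 and 0. By the rule for genes set apart at a stage, which needs both contrasts of a stage to pass, DE, PE and E each had 0, and E had 8 by DESeq2, 968 without E replicate 3 and 2 without DE replicate 3. With edgeR the E to PE count was 1847 without E replicate 3, 279 without PE replicate 2 and 1 without PE replicate 4, and the DE to E count was 1039 without E replicate 3 and 2 without DE replicate 3. Without DE replicate 3 and E replicate 3, a fit chosen after seeing the data, 2656 genes passed for E against PE, 2750 for DE against E and 2137 were set apart at E. The oviduct index as a covariate, also added afterwards, gave 3 genes for E against PE, all higher, 4 for DE against E, all lower, and 3 set apart at E. The groups did not overlap in 0.9%, 8.9% and 2.9% of genes, where chance gives 2.86%.

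Lists differed between stages with the preset correlation in 11, 11 and 12 cases and in 0 with an estimated one, and no list had a member past the threshold over all genes. From DE to PE, cell cycle genes were lower (camera adjusted p = 6.8e-13), cholesterol synthesis was lower (9.5e-07; 0.15 without DE replicate 3) and macrophage genes were higher (1.4e-06), each with 0 members adjusted over the list alone and adjusted p = 0.53 with an estimated correlation. With the oviduct index as a covariate, a fit added after seeing the data, cell cycle (3e-05) and macrophage (0.00063) passed and cholesterol synthesis (0.16) did not. From PE to E, oocyte (5.2e-11), cell cycle (2.4e-10), cholesterol synthesis (6.4e-07) and luteal genes (1.7e-05) were higher, with 0, 0, 0 and 5 members adjusted over the list alone and adjusted p = 0.56 with an estimated correlation for each. The oviduct index was 5.24 at PE and 2.06 at E on average; with it as a covariate, cell cycle passed (0.0095), oocyte (0.23) and luteal genes (0.23) did not, and cholesterol synthesis turned to lower (0.25). Oviduct epithelium was lower at E than at PE (3e-11, 0 members adjusted over the list alone, adjusted p = 0.56 with an estimated correlation) and higher at DE than at E (5.3e-09, 0 members, adjusted p = 0.59 with an estimated correlation). Oocyte genes were lower at DE than at E (8e-17), and smooth muscle (4.5e-06) and adipocyte genes (8.1e-05) higher, with 0 members each adjusted over the list alone and adjusted p = 0.59 with an estimated correlation. With the covariate, oocyte (1.2e-07) and adipocyte genes (0.0021) passed and smooth muscle (0.093) did not. The mitochondrial genome list, which tracks RNA quality, was lower from DE to PE (0.0017) and higher at DE than at E (0.0014), with 0 members each adjusted over the list alone and adjusted p = 0.53 and 0.59 with an estimated correlation. Its calls ended without DE replicates 1 (0.4) or 2 (0.061) or PE replicate 1 (0.078), and without E replicate 3 (0.1).

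**Figure D3:**
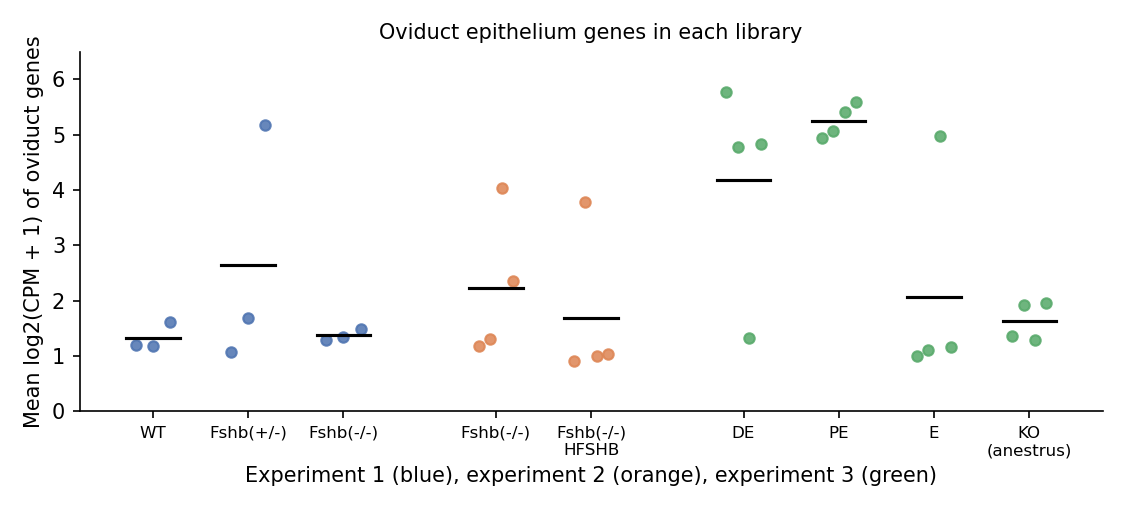
Oviduct index, the mean log2(CPM + 1) of the fixed oviduct epithelium list, in each of the 33 libraries by group, with 1 point per library. DE replicate 3 lies at 1.33 while the other DE libraries lie at 4.77 to 5.77, and E replicate 3 lies at 4.97 while the other E libraries lie at 1 to 1.16.

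The changes against the libraries labelled Fshb(-/-) in experiment 1 were set against experiment 3, which shares no library with it. Of 1315 genes called in experiment 1 and tested in experiment 3, the sign of WT over Fshb(-/-) was that of the stage over KO (anestrus) in 94.1% at DE, 92.9% at PE and 95.9% at E. The log2 fold changes had Pearson r of 0.57, 0.51 and 0.64 and Spearman rho of 0.52, 0.49 and 0.58 across genes, and with the contrasts between stages Pearson r was -0.07, 0.07 and -0.03. Sets called higher in both held 348, 364 and 341 genes, where independent lists would share 68.3, 88.2 and 51.6, and sets called lower in both held 479, 540 and 392, where they would share 91.0, 128.1 and 70.5.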

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

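Of the tests in this part, those of oviduct tissue by cilia genes and of exchanged labels were set out before their results were seen, and all others, the splits included, were chosen only afterwards.

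In the groups of 4 libraries, 14 quantities (the total count, the oviduct index and the 12 panel genes) were searched in each of 6 groups for a library far from the other 3. Of 84 searches 6 found one, where chance gives about 1 in 20. The oviduct index was 3.78 in Rescue replicate 2 (others 0.912 to 1.03) and 4.97 in E replicate 3 (others 1 to 1.16). Pgr was at 39.7 CPM in E replicate 3 (others 3.28 to 5.27). Lhcgr was at 57.6 CPM in PE replicate 4 (others 290 to 321). In PE replicate 2, Star was at 957 CPM (others 136 to 181) and Gdf9 at 34.7 CPM (others 54.9 to 59.5).

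Oviduct transcripts were high in 8 of the 12 libraries of the cycling stages: all of PE, DE replicates 1, 2 and 4, and E replicate 3. The stage of the cycle alone is argued against with the labels as given, since DE replicate 3 and E replicate 3 lie 3.44 and 3.81 from the nearest library of their stage, where the others span 1 and 0.16. Oviduct tissue collected with the ovary was tested with a set of motile cilia genes outside the oviduct list. Of these, 96.6% (28 of 29 tested) rose with the index against 11.6% of all genes. Dnah6 reached 81 CPM, against at most 4.32 in KO (anestrus). The oviduct list itself holds cilium genes such as Foxj1, Dnah5 and Rsph1, so other cilium genes would follow the index whatever its source. The rise of the cilia genes therefore does not by itself decide where the signal came from. Ovgp1, a list member that encodes an oviduct glycoprotein, was at 2970 to 7040 CPM in these 8 libraries. In the other libraries of experiment 3 it was at most 35.6 CPM. Such values go with oviduct tissue in the samples, although Ovgp1 is part of the index and was not tested apart from it. Exchanged labels of DE replicate 3 and E replicate 3 stay open: over 1249 genes that part the other DE and E libraries, DE replicate 3 was nearer E in 86.3% and E replicate 3 nearer DE in 67.4%, although oviduct carry-over was not fully removed from those genes. If the labels were exchanged, the index would follow the stage, and its link to the stage, biological or from dissection, could not be told from these libraries.

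Fshb had more than 3 counts in 9 of the 12 libraries of experiment 3 labelled WT, at 2.58 to 15 CPM. Inhba argues against Fshb(-/-) ovaries without the transgene as the source of these 9, but cannot tell them from Fshb(-/-) ovaries with it. Its lowest value among them was 5.23 times the highest in the libraries labelled KO (anestrus) (142 against 27.1 CPM with TMM-scaled library sizes). The rescue libraries, labelled Fshb(-/-) HFSHB, also had high Inhba (854 to 1360 CPM of the total count) along with Fshb reads. High Inhba thus sets the 9 apart from the KO (anestrus) libraries, whose own genotype label reads WT, but not from the rescue. Libraries labelled Fshb(-/-) without HFSHB, all of other experiments, also lay below the 9. They reached at most 41.5 CPM of the total count in experiment 1 and 19.1 in experiment 2. A constant share of reads from elsewhere assigned to Fshb is argued against by the 6 libraries of experiments 1 and 3 with 0 to 3 Fshb counts, all with a total of at least 12.3 M. Whether the 9 may carry 1 targeted allele cannot be told apart: 5 of the 9 lie within the range of the libraries labelled Fshb(+/-), 2.63 to 6.71 CPM, and counts per gene do not separate the alleles.

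The distance from the libraries labelled Fshb(-/-) differed between experiments 1 and 2 in 28 genes by a test of the difference, and in Fshb by 7.81. Whether the response to the transgene was incomplete is not decided by these genes, which were called because their 2 effects differ. Only 4% of 25 genes had a rescue effect between 0 and the WT effect, and 18 had opposite signs. Some of the 18 had hardly any rescue effect, such as Gm6768 (10.12 for WT and -0.12 for the rescue). A difference in the origin of chromosome 2 between groups is consistent with 9 of 26 genes lying there besides Fshb (34.6% against 7.6% of tested genes, Fisher p = 8e-05), 7 of them between 119 and 123 Mb. Among them Jmjd7 was at 1.18 CPM in the libraries labelled Fshb(-/-) and 6.63 in WT of experiment 1, but at 5.55 in Fshb(-/-) and 0.859 in the rescue of experiment 2. The Fisher test takes genes as independent, which neighbours between 119 and 123 Mb need not be, so its p may be too small. Reads shared between near-identical copies may add to the differences, as 22.2% of 27 genes are pseudogenes against 4.6% of those tested (Fisher p = 0.0012). An excess of pseudogenes does not by itself show that reads were shared.

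Other splits of the libraries into groups of the same sizes were fitted for each comparison. In experiment 1 there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many genes each time, with 1355 genes for Fshb(-/-) against WT (highest other 0), 15 for Fshb(+/-) against WT (4) and 2928 for Fshb(-/-) against Fshb(+/-) (0). Among 35 splits the real one alone reached its count for the rescue against Fshb(-/-) (5390, highest other 2). The same held for DE (4249, 2), PE (5724, 0) and E (3042, 0) against KO (anestrus). A share of 1 in 35, the smallest possible here, makes chance unlikely but does not exclude it. The comparisons with KO (anestrus) share its libraries, and the splits treat libraries as separate animals, which the labels do not say. Between the stages edgeR called 0 genes, so that all 35 splits have as many by construction, and this says nothing about chance. The highest other was 146 for PE against DE, 404 for E against PE with PE replicate 2 and E replicate 3 exchanged, and 3212 for DE against E with DE replicate 3 and E replicate 3 exchanged, which points to a structure of the samples other than their labels. For genes set apart at DE, PE and E the real count is also 0, so all 100 drawn splits have as many and nothing follows about chance (highest others 2, 2606 and 5). The 2606 came from a split with DE replicate 3 among E replicates 1, 2 and 4, which points to the same structure. For the difference between experiments 1 and 2, 2 of 100 splits reached the real 28. The other reached 1824, in a split that mixes WT and Fshb(-/-) libraries of experiment 1 so that the effects of both experiments add up, a structure of the samples as well. Splits within each experiment also break up the effect of each, so they do not stand for 2 equal effects. The share of splits therefore says nothing about chance for the 28 genes.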

How the results depend on the processing

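The oviduct index as a covariate and the fits without DE replicate 3 and E replicate 3 were chosen only after the results were seen; all other alternatives were planned. Of 298 results for named genes, 198 kept their direction and side of the threshold under every alternative run, and 217 under every planned one. Median-of-ratios factors kept 298 of 298, a mean CPM of at least 1 kept 297, DESeq2 283 of 298 (15 newly past the threshold), no filter 278 (20 lost), limma voom 259 (28 lost), only the groups compared 212 of 227 (10 lost), and the covariate 260 of 298 (27 lost). With 1 library left out, 2121 of 2278 values kept their side and 134 lost it. All 124 list calls were lost with an estimated correlation, and 124 kept with median-of-ratios factors. With 1 library left out 836 of 930 kept and 90 were lost, and with the covariate 84 of 124 kept and 24 were lost. Counts of genes stayed within 1.5 times with median-of-ratios factors (15 of 15), no filter (14 of 14), a mean CPM of at least 1 (14 of 14), only the groups compared (10 of 10) and a fit of the 3 cycling stages alone (3 of 3). Depth limits weak genes, as a count of 0 in the smallest library, of 10.1 M counts, allows up to 3. For the changes below, the cause was not tested.

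limma voom called 3280 genes for Fshb(-/-) against WT, 29 for Fshb(+/-) against WT, 2251 for E against PE, 5221 for E against KO (anestrus) and 58 for the difference between experiments 1 and 2. DESeq2 called 2379 for Fshb(-/-) against WT, 363 for Fshb(+/-) against WT, 363 for E against PE, 10 for DE against E, 135 for the difference, 8 for genes set apart at E, and 1936 in one direction in both experiments 1 and 2. With the oviduct index as a covariate the counts were 3 for E against PE, 4 for DE against E, 1618 for DE and 934 for PE against KO (anestrus), and 3 for genes set apart at E. Without DE replicate 3 and E replicate 3 they were 2656 for E against PE, 2750 for DE against E and 2137 for genes set apart at E. With 1 library left out, counts ranged from 456 to 1030 for Fshb(-/-) against WT, 9 to 14 for Fshb(+/-) against WT, 1362 to 2581 for Fshb(-/-) against Fshb(+/-), 0 to 1847 for E against PE, 0 to 1039 for DE against E, 2422 to 5787 for DE and 1920 to 2779 for E against KO (anestrus), 18 to 30 for the difference, and 0 to 968 for genes set apart at E.

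With the covariate, the direction turned in these lists (adjusted p): oviduct epithelium, whose mean is the covariate so that its loss is fixed by construction, in Fshb(+/-) against WT (0.45), in PE against DE (0.83) and in DE (0.56) and PE (0.45) against KO (anestrus); ovarian surface epithelium in PE against DE (0.25), E against PE (0.0033), DE against E (0.0084) and DE (0.62) and PE (0.42) against KO (anestrus). It also turned in steroidogenesis (0.28), granulosa and FSH response (0.56), cholesterol synthesis (0.25) and smooth muscle (0.72) in E against PE, in steroidogenesis (0.94), cell cycle (0.93) and cholesterol synthesis (0.0084) in DE against E, and in A2ml1 in PE against KO (anestrus), at -0.98. Ovarian surface epithelium in PE against DE turned without DE replicate 3 and E replicate 3 (0.52). With 1 library left out, adjusted p ranged from 0.001 to 0.86 for macrophage and 6e-12 to 0.82 for oviduct epithelium in Fshb(+/-) against WT, from 0.0021 to 0.97 for ovarian surface epithelium in PE against DE and from 8.1e-06 to 0.26 for cell cycle in DE against E, and the direction turned at the highest value of each.

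Replicate numbers do not pair the libraries, as same-number correlations ran from -0.77 to 0.28. With the number as a block, 12 of 13 counts stayed within 1.5 times, the other being 7 for Fshb(+/-) against WT, 267 of 286 results for genes and 124 of 124 list calls kept their side, and the cause was not tested.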

Other observations

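The fit with the oviduct index as a covariate was chosen only after the results were seen, and no explanation was tested in this part. In the rescue ovaries, genes of oxidant defence moved both ways, with 6 of 23 higher and 4 lower and no call for the list (edgeR and camera, adjusted over all genes): the glutathione transferase gene Gsta3 fell (log2 fold change -3.29 ± 0.22, n = 4 each), while Srxn1, which repairs oxidized peroxiredoxins (1.49 ± 0.11), and the heme oxygenase gene Hmox1 (1.01) rose. Genes known to be induced by the LH surge were split as well, with 6 of 26 higher and 9 lower; Has2 (-4.02 ± 0.23) and the prostaglandin synthase gene Ptgs2 (-2.90 ± 0.32) fell. The immediate early genes Nr4a1 (-1.44) and Btg2 (-0.89) fell, the 2 of 19 that passed. Among endothelium genes, Vwf, which encodes von Willebrand factor, fell (-0.95 ± 0.11) although most of the list rose. The macrophage genes Mpeg1 (1.52) and Cd68 (1.16) rose.

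Against KO (anestrus), fibrillar collagen and matrix genes were higher in 6, 5 and 5 of 20 at DE, PE and E (7, 5 and 5 adjusted over the list alone), with Fn1 at 2.25, 2.34 and 1.59 and Thbs2, which encodes thrombospondin 2, at 1.57 at PE and 1.38 at E. Camera gave adjusted p = 0.00017, 0.0028 and 0.013, and adjusted p = 0.52, 0.53 and 0.85 with an estimated correlation; its call at E ended without E replicate 4 (0.14). Glycolysis and hypoxia genes were higher in 5, 6 and 6 of 22, the same adjusted over the list alone, with the angiogenic factor gene Vegfa at 1.54, 1.38 and 1.97. Here camera gave adjusted p = 0.0043, 0.012 and 0.0033, and adjusted p = 0.52, 0.54 and 0.65 with an estimated correlation. Its call at PE ended without PE replicate 2 (0.077), and with the oviduct index as a covariate it had adjusted p = 0.15 at DE and 0.48 at PE. Adipocyte genes were higher in 4 of 13 at DE and 7 at PE (12 and 11 adjusted over the list alone; adjusted p = 4.2e-05 and 0.00012, and adjusted p = 0.52 and 0.53 with an estimated correlation), with Plin4 at 3.89 and 3.05. At E 1 of 13 was higher, also adjusted over the list alone (adjusted p = 0.034, and adjusted p = 0.89 with an estimated correlation), and the list call ended without E replicate 4 (0.29) or KO replicates 1 (0.26), 3 (0.093) or 4 (0.062). At E it had adjusted p = 0.052 with the oviduct index as a covariate. KO replicate 2, with a mean of 5.13 over the list, lies within the range of the stages (3.73 to 7.32).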
